A study of Arabidopsis thaliana with 12 samples.

How the data were processed

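Leaf RNA was measured in 12 libraries of Arabidopsis thaliana, 3 for each of 4 genotypes: the Col-0 wild type (WT), the smg7-6 mutant, the cdkd3-1 mutant and the cdkd3-1/smg7-6 double mutant. Per the labels' protocols, plants were grown in soil under long days, leaves of 5 plants aged 3 weeks were pooled for each library, ribosomal RNA was depleted from the total RNA, and strand-specific libraries were made with a kit for plant leaves. The labels speak of biological replicates for the experiment and of a technical replicate for the pool of plants, so the spread between libraries is that between pools of plants; the labels give the plants of a pool as grown at the same time and say no more on the pools.

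The deposited values are TPM, scaled for gene length and library total, for 33681 gene identifiers, and the values of each library sum to 1e+06. Per the submitters' processing notes, the tools included bcl2fastq 2.20.0.422, cutadapt 2.5 and Salmon 1.5. The genome build, the transcript annotation, the filters and the step from transcripts to genes are not given in the sources used here. TPM keeps no depth, so the number of reads behind each value is unknown and no counting interval or detection floor was computed. A value of 0 means only that a gene is listed at 0. How reads shared by similar copies were assigned is not given either, so values of near-identical genes, such as the glucanases BG3 and BGL2, the PCR1 and PCR2 pair, the CRK receptor kinases and the light-harvesting genes, are uncertain. No coordinates are printed. The TAIR10.1 reference annotation was used only for names, gene classes and neighbours, and 32954 of the identifiers matched it; it does not pair plastid identifiers with names, so at most 2 plastid identifiers that rose and 2 that fell are printed.

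The main test, fixed before the data were examined, was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with 1 mean per genotype over all 12 libraries and empirical Bayes moderation with a trend of the variance. Genes with a TPM of at least 1 in at least 3 libraries entered, which left 14968. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Fold changes are on this log2 scale, and the pseudocount of 1 understates the change of low genes. On this scale the moderation gave an infinite prior, so that a gene's own spread did not count in its standard error or p. Both rest on the trend of the variance alone. On the median-of-ratios scale the prior had 3.41 degrees of freedom against 8 residual ones. A call lost after that scaling may therefore be lost to the moderation: with 3.41 prior degrees of freedom on the deposited scale, smg7-6, cdkd3-1 and the double mutant against WT had 2, 3 and 3 called genes, and with an infinite prior on the median-of-ratios scale 1691, 715 and 2171. The contrasts were: each mutant against WT, the double mutant against each single mutant, the interaction of the mutations, and the effect of each mutation averaged over both backgrounds.

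The libraries differ in how much of the TPM is taken by plastid RNA, so the TPM of nuclear genes moves as a block. The log2 change of the median gene is therefore given for each comparison, changes are reported relative to it, and counts are printed beside those after median-of-ratios scaling of the libraries over nuclear genes, whose factors ran from 0.349 to 1.73. Other alternatives were pseudocounts of 0.1 and 2, no filter, a filter at 5 TPM, rescaling to nuclear genes, quantile normalization, a fit on the compared groups only, array weights, moderation without the trend, a replicate block, and leaving out each library in turn. Without cdkd3-1 replicate 1 the prior fell from infinite to 7.05 degrees of freedom, so gene calls lost without it may be lost to the moderation. Chosen after the data had been seen were median-of-ratios scaling with the block, and leaving out both libraries with the most of plastid identifier ATCG00970, cdkd3-1 replicate 1 and double mutant replicate 3, on either scale, and exchanging the prior degrees of freedom between the 2 scales.

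The labels give every genotype replicates 1, 2 and 3. Deviations from the genotype means correlated above 0.1 for every same-numbered pair in 4 of the 5 comparisons of 2 genotypes, for instance from 0.493 to 0.813 in the double mutant against WT. In the double mutant against cdkd3-1 the lowest pair was 0.0321. Over all genotypes 16 of 18 such pairs were above 0.1, from -0.0564 to 0.813, and all 12 libraries correlated best with one of their own number. The pairing thus comes from the numbers in the labels and this check, not from a stated shared day.

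Genes were named by a rule fixed before the data were examined. SMG7 and CDKD;3 come first. For each mutant against WT the rule takes up to 10 called genes per direction with the largest change, no overlap between the libraries of the 2 groups and a mean of at least 5 TPM in the higher group. For the double mutant against each single mutant and for the interaction it takes up to 5 per direction. The requirement of no overlap has no meaning for the interaction and was left out there. Plastid and mitochondrial genes and structural RNA genes were kept out of this ranking. From each gene list up to 4 members with the smallest p could be named.

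The 31 gene lists, fixed beforehand from textbook knowledge, hold 411 entries; 390 were matched by identifier, 5 by another name of the gene and 16 had no reference name, and 2 are not among the measured identifiers. The reference gives the symbol MAT1 to a methionine adenosyltransferase, so the assembly factor of the CDK-activating kinase was kept by its identifier, AT4G30820, a departure from the written matching rule. Lists with at least 5 tested members (22, and 24 with the plastid and mitochondrial genomes) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists in each contrast, and again with an estimated correlation and with fry. The fry p asks whether a list's genes move, on balance, in 1 direction, and does not compare them with other genes. No list call on the deposited scale held with an estimated correlation or with fry. On the median-of-ratios scale, the fry calls that were made are given with each list.

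The analysis steps were tested on simulated data made for smg7-6 against WT with 200 of 14968 genes changed. The changed genes were drawn only from the more highly expressed ones, so the shares below say nothing on genes near the filter. On the deposited scale, 25.37% of genes changed 2-fold, 85.07% changed 4-fold and 95.45% changed 8-fold were recovered, with 7 unchanged genes called. With median-of-ratios scaling the shares were 37.31%, 82.09% and 93.94%, with 9 unchanged genes called. The simulated noise was independent between libraries, which the real noise is not. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.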

Results

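The transcriptome of leaves was compared between WT, the smg7-6 and cdkd3-1 mutants and the cdkd3-1/smg7-6 double mutant, with 3 libraries per genotype. SMG7 is a factor of nonsense-mediated mRNA decay that plants also need to leave meiosis, and CDKD;3 is a CDK-activating kinase, which phosphorylates other cyclin-dependent kinases and the tail of RNA polymerase II. CDKD;3 (AT1G18040) was at 1.42, 0.491 and 0.611 TPM in WT replicates 1 to 3 and at 0.864, 0.496 and 0.594 TPM in smg7-6, and it was listed at 0 in all 6 libraries labelled with cdkd3-1. It lay below the filter and was not tested. SMG7 (AT5G19400) was at 4.35 ± 2.001 TPM (SD, n = 3) in WT, 2.40 ± 0.560 in smg7-6, 2.16 ± 1.07 in cdkd3-1 and 2.05 ± 0.935 in the double mutant. Its log2 difference from WT in smg7-6, -0.61 with a standard error of 0.378, did not pass the test (limma adjusted p = 0.996), and after median-of-ratios scaling the difference of the double mutant from WT did (adjusted p = 0.0349).

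Plastid RNA made up 65.5% to 85.3% of the TPM of a library and nuclear protein-coding genes 7.78% to 31.8%. The lowest share of nuclear protein-coding genes was in cdkd3-1 replicate 1, where the plastid identifier ATCG00970 alone held 43.6% of the TPM. Nuclear ribosomal RNA reached 5.26% in double mutant replicate 3 and was as low as 0.0318% in another library. The number of genes at 1 TPM or more ran from 8330 to 15459. Across genes, Spearman correlations between libraries ranged from 0.883 to 0.976 within a genotype and reached 0.972 between genotypes. The sequencing depth of the libraries is unknown.

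**Figure D1:**
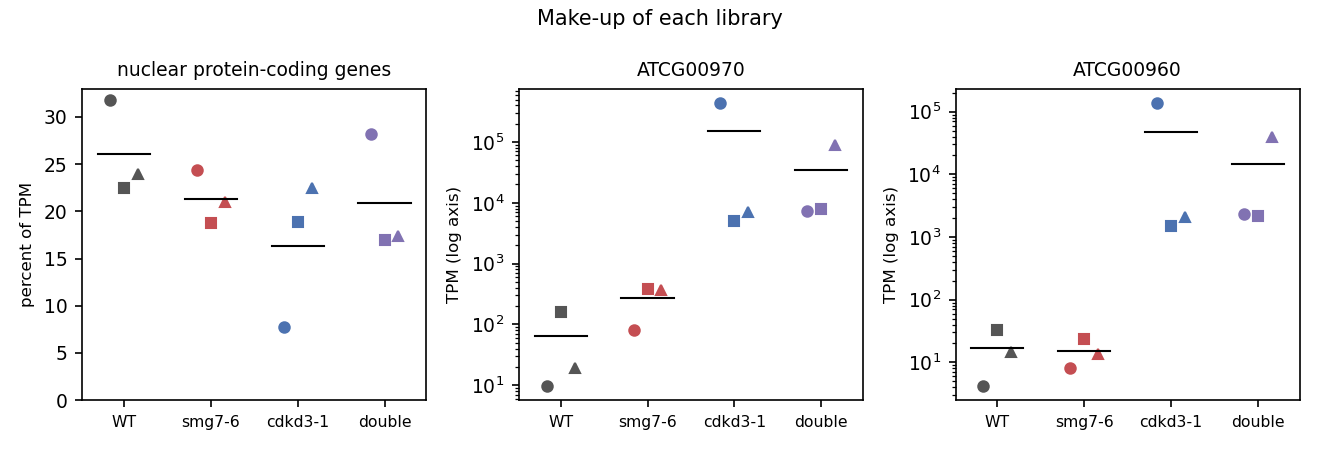
Percent of TPM in nuclear protein-coding genes (linear axis from 0) and TPM of 2 plastid identifiers (log axes) in each library; points are libraries by genotype, circles, squares and triangles are replicates 1, 2 and 3, and lines are genotype means. Nuclear protein-coding genes fell to 7.78% in cdkd3-1 replicate 1, where ATCG00970 stood at 436150 TPM.

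In leaves of smg7-6, genes of the immune response rose against WT. The largest increase among the named genes was that of PR1, a pathogenesis-related protein used as a marker of the salicylic acid response, at 164 ± 107 TPM against 12.2 ± 17.9 TPM in WT (SD, n = 3), a log2 change of 4.49 relative to the median gene with a standard error of 0.555 (limma adjusted p = 2.96e-11). PCR1, a cysteine-rich membrane protein of the cadmium resistance family, stood at 425 ± 210.5 against 45.3 ± 16.3 TPM (adjusted p = 3.04e-04). NIMIN1, which binds the salicylic acid receptor NPR1, was at 35.4 ± 15.8 against 5.49 ± 0.340 TPM (adjusted p = 8.92e-04), and BG3, a beta-1,3-glucanase, at 27.8 ± 16.3 against 3.51 ± 1.04 TPM (adjusted p = 7.33e-05). LURP1, which takes part in defence against an oomycete, was at 187 ± 75.6 against 31.4 ± 10.7 TPM (adjusted p = 0.00752). The increases were uneven between pools, and smg7-6 replicate 2 was the lowest of its group in each of these genes. PR1 stood at 245, 43.1 and 203 TPM in smg7-6 replicates 1 to 3, against 32.9 TPM in WT replicate 2. The other named increases were AT1G75945, AT1G13470 of the DUF1262 family, the noncoding RNA genes AT3G15536 and AT4G04223, and AT1G58225, with log2 changes of 2.498 to 3.41 relative to the median gene. Of these 10 increases, those of PR1, AT4G04223 and AT1G58225 did not pass after median-of-ratios scaling (adjusted p = 0.0725, 0.101 and 0.135). With the prior degrees of freedom of that scale, none of the 10 passed on the deposited scale. PR1, PCR1, NIMIN1, BG3 and LURP1 then had limma adjusted p of 0.675, 0.519, 0.427, 0.695 and 0.627.

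Named decreases in smg7-6 were 4. AT3G01345 was at 27.9, 6.999 and 7.06 TPM in the WT libraries and at 0.0277, 0.211 and 0.0624 TPM in those of smg7-6, a log2 change of -3.31 relative to the median gene (SE 0.294, adjusted p = 3.46e-28). MRD1, a gene named for its low expression in a methionine-overaccumulating mutant, was at 13.0 ± 3.20 TPM in WT and 0.642 ± 0.164 TPM in smg7-6 (adjusted p = 9.75e-17). The microRNA gene MIR775 and AT1G14250, of a nucleoside phosphatase family, stood at 8.90 ± 2.93 and 8.98 ± 1.12 TPM in WT against 2.78 ± 2.58 and 2.52 ± 2.08 TPM, with adjusted p of 0.00752 and 0.00986 that became 0.352 and 0.150 after median-of-ratios scaling.

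**Figure D2:**
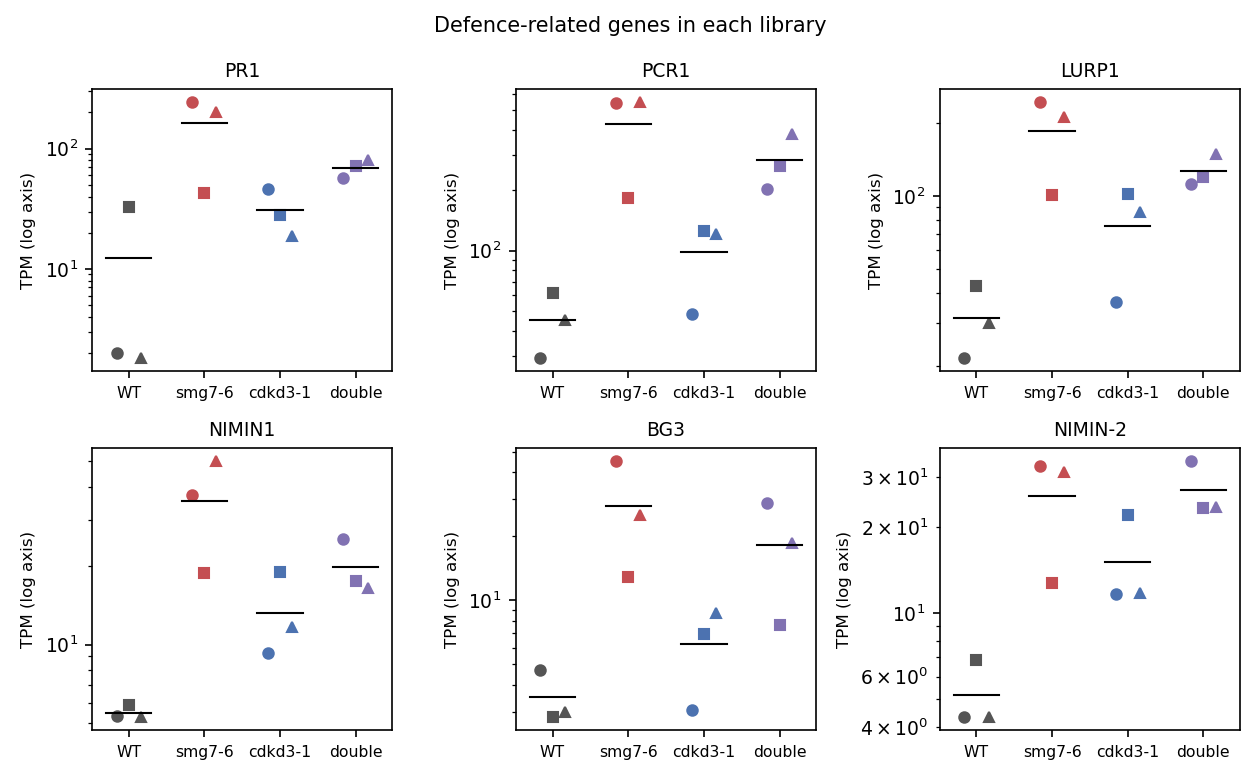
TPM (log axes) of PR1, PCR1, LURP1, NIMIN1, BG3 and NIMIN-2 in each library by genotype; circles, squares and triangles are replicates 1, 2 and 3, and lines are genotype means of 3 libraries. NIMIN1 lay between 5.27 and 5.88 TPM in WT and between 18.8 and 50.2 TPM in smg7-6, while PR1 reached 32.9 TPM in WT replicate 2 against 1.81 TPM in WT replicate 3.

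Among the lists, the salicylic acid and immune response genes stood highest: all 18 measured members changed by more than the median gene, with a median log2 change of 1.18 above it. PR1, PCR1, NIMIN1 and BGL2, another beta-1,3-glucanase, passed over all genes and 6 members passed adjusted over the list alone, all of them higher, while the other 12 did not. Camera gave the list an adjusted p of 1.76e-37, and the adjusted p = 0.0917 with an estimated correlation; after median-of-ratios scaling fry gave 0.0221 and 18 members passed adjusted over the list alone. The rapid stress and touch genes were called higher (14 members, adjusted p = 6.50e-08; adjusted p = 0.589 with an estimated correlation), with WRKY53 the only member to pass adjusted over the list alone and none over all genes. The mitotic cell cycle and replication genes were called lower (29 members, 1 above the median gene, adjusted p = 1.31e-06; adjusted p = 0.912 with an estimated correlation). Of these the Aurora kinase AUR2 and the B-type cyclin CYC1BAT passed adjusted over the list alone, and none passed over all genes. Of 8 cytokinesis genes, 5 were lower adjusted over the list alone and 0 over all genes, among them the cytokinetic syntaxin SYP111 (KNOLLE) at 3.63 ± 1.43 against 9.53 ± 0.857 TPM, the kinesins HIK and KINESIN-12B, and the microtubule bundler PLE (camera adjusted p = 0.00577; adjusted p = 0.836 with an estimated correlation).

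The heat shock and protein folding genes (5 members, adjusted p = 6.92e-05) and the senescence genes (5 members, adjusted p = 0.0106) were called higher in smg7-6. The first had an adjusted p = 0.535 with an estimated correlation and the second an adjusted p = 0.823. The nuclear photosynthesis genes, such as those of the light-harvesting antenna, and the cold and abscisic acid genes were both called lower with an adjusted p of 0.0116 (22 and 9 members). These had an adjusted p = 0.985 and an adjusted p = 0.836 with an estimated correlation. No member of these 4 lists passed over all genes; adjusted over the list alone, 1 senescence gene, SAG21, passed and none of the others did. In the photosynthesis genes WT replicate 1 stands apart from the other WT libraries, with RCA, which activates the carbon-fixing enzyme, at 1586 TPM against 279 and 228 TPM in WT replicates 2 and 3 and 405, 223 and 195 TPM in smg7-6. Replicate 1 of the double mutant was as high, with RCA at 1476 TPM against 154 and 175 TPM in its replicates 2 and 3. In cdkd3-1 replicate 1 was the lowest, at 113 TPM against 190 and 246 TPM. The camera call of the photosynthesis list was lost without WT replicate 1 (adjusted p = 0.796), that of the cold genes without WT replicate 2 (0.730) and that of the senescence genes without smg7-6 replicate 3 (0.221). After median-of-ratios scaling the calls of the senescence and cold lists were lost (adjusted p = 0.190 and 0.240), and the 5 heat shock genes passed adjusted over the list alone (fry adjusted p = 0.0452).

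Over all genes, smg7-6 against WT gave 102 calls, 75 higher and 27 lower, with the median gene at -0.18. Protein-coding genes made up 64 of the increases and 5 of the decreases, and 12 of the decreases were small nucleolar RNA genes. After median-of-ratios scaling 136 genes were called, 128 higher and 8 lower, and 33 were called on both scales. The count on the deposited scale was 48 without WT replicate 1, 49 (22 higher and 27 lower) without WT replicate 3, 41 without smg7-6 replicate 1 and 28 without smg7-6 replicate 3. Of the 15 named genes called, 9 passed without each library in turn; LURP1, NIMIN1, AT1G58225, MIR775, AT1G14250 and BGL2 did not, with adjusted p of 0.260, 0.154, 0.513, 1.00, 1.00 and 0.267 without smg7-6 replicate 3.

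In cdkd3-1 few nuclear genes outside the structural RNAs were called against WT on the deposited scale. AT3G01345 was listed at 0 in all 3 cdkd3-1 libraries (WT libraries at 27.9, 6.999 and 7.06 TPM; adjusted p = 4.50e-31), and MRD1 was at 0.0943 ± 0.0519 TPM against 13.0 ± 3.20 TPM (SD, n = 3; log2 change of -3.06 relative to the median gene, adjusted p = 6.37e-25). TPPI, a trehalose-6-phosphate phosphatase, was at 0.740 ± 0.537 TPM against 8.45 ± 3.22 TPM (log2 change of -1.85 relative to the median gene, SE 0.392, adjusted p = 4.93e-07). After median-of-ratios scaling its log2 change was -2.03 and it did not pass (adjusted p = 0.103), but the moderation of the variances changes with the scaling: with the prior degrees of freedom of that scale it did not pass on the deposited scale either (adjusted p = 0.286), and with an infinite prior it passed after the scaling (adjusted p = 1.00e-35). AT1G75945 was higher, at 1.95, 8.62 and 12.2 TPM in the cdkd3-1 libraries against 0, 0.0934 and 0.191 TPM in WT (adjusted p = 5.78e-08). PR1 was called too, at 31.0 ± 13.9 against 12.2 ± 17.9 TPM (adjusted p = 0.0289), and not after median-of-ratios scaling (adjusted p = 0.922).

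**Figure D3:**
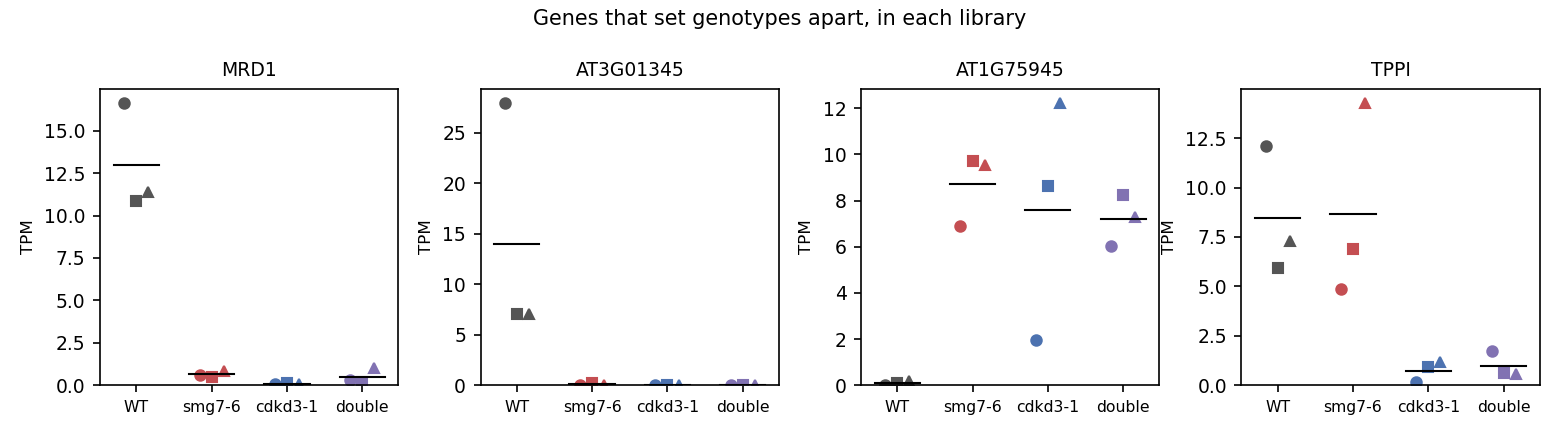
TPM (linear axes from 0) of MRD1, AT3G01345, AT1G75945 and TPPI in each library by genotype; circles, squares and triangles are replicates 1, 2 and 3, and lines are genotype means of 3 libraries. MRD1 was at 10.9 to 16.6 TPM in WT and at most 1.02 TPM in the 9 mutant libraries, and TPPI was at most 1.73 TPM in the 6 libraries with cdkd3-1.

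Plastid transcripts gave the largest differences of cdkd3-1 from WT. ATCG00970 and ATCG00960, which are plastid ribosomal RNA genes, rose by 10.15 and 9.67 on the log2 scale relative to the median gene (adjusted p = 3.33e-45 and 4.11e-42), and both had every cdkd3-1 library above every WT library. Their levels were very uneven: ATCG00970 stood at 436150, 4944 and 7002 TPM in the 3 cdkd3-1 libraries and at 9.66, 163 and 19.1 TPM in WT, and after median-of-ratios scaling neither passed (adjusted p = 0.222 and 0.229). ATCG00620 fell from 81.3 ± 22.8 to 5.13 ± 0.936 TPM (adjusted p = 1.70e-09; 0.0648 after median-of-ratios scaling) and ATCG00410 from 223 ± 27.6 to 40.7 ± 29.9 TPM (adjusted p = 5.28e-04; 0.566 after that scaling). Of 114 plastid genes 7 passed over all genes, 3 of them higher, and 13 adjusted over the list alone. The list was not called in camera (adjusted p = 0.0689) but was called lower with the replicate block (adjusted p = 1.24e-04), as were the mitochondrial genes with the block (64 members, 0.0468 against 0.783 without it).

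The salicylic acid and immune response genes were called higher in cdkd3-1 as well (17 of 18 members above the median gene, adjusted p = 1.21e-23; adjusted p = 0.220 with an estimated correlation). PR1 was the only member to pass, both over all genes and adjusted over the list alone. After median-of-ratios scaling 0 passed over all genes and 7 adjusted over the list alone (fry adjusted p = 0.291). The rapid stress and touch genes (14 of 14 above the median gene, adjusted p = 7.33e-16; adjusted p = 0.220 with an estimated correlation) had no member that passed either way. The mitotic and replication genes were called lower (adjusted p = 0.00239; adjusted p = 0.973 with an estimated correlation), with 14 of 29 lower adjusted over the list alone and 0 over all genes, among them CDKB2;1, AUR2 and CYCA1;1, and 0 adjusted over the list alone after median-of-ratios scaling. The nuclear photosynthesis genes were called lower (adjusted p = 3.75e-04; adjusted p = 0.973 with an estimated correlation), and the senescence and heat shock genes higher (adjusted p = 0.00183 and 0.00269; both at an adjusted p = 0.614 with an estimated correlation), with no member passing. For the last pair fry, which does not compare with other genes, had the opposite sign (adjusted p = 0.790 and 0.752). Of the cytokinesis genes, whose list was not called (adjusted p = 0.104), 6 of 8 were lower adjusted over the list alone. After median-of-ratios scaling the cytokinesis list was called lower (adjusted p = 0.00674), with 0 members passing adjusted over the list alone, and the senescence call was lost (0.215). Without WT replicate 1, which stands high in photosynthesis genes, their call was lost (0.121), as were the heat shock call without cdkd3-1 replicate 1 (0.0731) and the mitotic call without cdkd3-1 replicate 3 (0.0788).

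Over all genes, 42 were called in cdkd3-1 against WT, 14 higher and 28 lower, with the median gene at -0.59; with array weights 2094 were, 200 higher and 1894 lower, and with median-of-ratios scaling and an infinite prior 715, 572 higher and 143 lower, so that neither direction prevailed throughout. Organelle genes and structural RNA made up 31 of them, including 11 small nucleolar RNA genes, and 9 were protein-coding. After median-of-ratios scaling only AT1G75945, MRD1 and AT3G01345 were called, 1 higher and 2 lower, with 627 genes at an unadjusted p under 0.05. Without cdkd3-1 replicate 1 the count on the deposited scale was 8, and the calls of TPPI and PR1 were lost (adjusted p = 0.166 and 0.727).

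In the double mutant, immune genes again stood above WT. PR1 was at 69.5 ± 11.7 against 12.2 ± 17.9 TPM (SD, n = 3; log2 change of 3.58 relative to the median gene, SE 0.555, limma adjusted p = 9.28e-07; 0.121 after median-of-ratios scaling), PCR1 at 282 ± 90.06 against 45.3 ± 16.3 TPM (adjusted p = 0.00583), and NIMIN-2, another partner of NPR1, at 27.0 ± 6.19 against 5.18 ± 1.47 TPM (adjusted p = 0.00399). AT5G10760, an apoplastic aspartyl protease of the EDS1 immune pathway, was at 55.1 ± 19.2 against 9.84 ± 5.05 TPM (adjusted p = 0.00220), and AT3G47480, an EF-hand calcium-binding protein, at 27.2 ± 7.09 against 5.91 ± 2.66 TPM (adjusted p = 0.00736). AT1G75945, AT1G13470, AT3G15536, AT1G58225 and the pseudogene AT4G04293 completed the named increases, with log2 changes of 2.26 to 3.07 relative to the median gene. Named decreases were AT3G01345, MRD1 at 0.502 ± 0.451 TPM, TPPI at 0.982 ± 0.648 TPM (adjusted p = 8.01e-06), the transfer RNA pseudogene AT3G20365, AT1G14250 and AT1G55335. After median-of-ratios scaling PR1, AT3G15536, AT1G58225, AT3G47480, AT3G20365, AT1G14250 and AT1G55335 no longer passed, with adjusted p from 0.0636 to 0.2503. With the prior degrees of freedom of that scale, only AT3G01345 and MRD1 of the named genes passed on the deposited scale. The plastid identifiers ATCG00970 and ATCG00960 rose by 9.22 and 8.90 relative to the median gene (adjusted p = 3.51e-40 and 1.02e-38; both 0.0520 after median-of-ratios scaling), and ATCG00620 fell to 6.63 ± 1.103 TPM (adjusted p = 9.52e-08).

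All 18 salicylic acid and immune response genes of the double mutant lay above the median gene, by a median of 1.195 (camera adjusted p = 7.05e-31; adjusted p = 0.157 with an estimated correlation; fry after median-of-ratios scaling 0.0298). PR1, PCR1 and BGL2 passed over all genes and 10 members adjusted over the list alone, all higher. Of the 14 rapid stress and touch genes, the transcription factors WRKY53 and WRKY40 and the deadenylase CAF1a passed over all genes and 6 adjusted over the list alone (adjusted p = 3.36e-18; adjusted p = 0.159 with an estimated correlation). SAG21 and SEN1 of the 5 senescence genes passed adjusted over the list alone and neither over all genes (adjusted p = 7.99e-05; adjusted p = 0.350 with an estimated correlation). The heat shock (adjusted p = 0.00481), glucosinolate (14 members, 0.00609) and jasmonate (13 members, 0.0131) genes were called higher, with no member over all genes and 1, 0 and 1 adjusted over the list alone. They had an adjusted p = 0.752, 0.839 and 0.839 with an estimated correlation. The jasmonate call was lost after median-of-ratios scaling (0.164) and without WT replicate 1 (0.227), the heat shock call without double mutant replicate 1 (0.0755) and the glucosinolate call without WT replicate 3 (0.0603).

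Lists called lower in the double mutant were the mitotic and replication genes (adjusted p = 3.92e-06), the nuclear photosynthesis genes (2.04e-04), the cytokinesis genes (0.00457) and the cytokinin primary response genes, which are response regulators (6 members, 0.00609). Each of these 4 lists had an adjusted p = 0.839 with an estimated correlation. No member passed over all genes; adjusted over the list alone, AUR2 and CYCA1;1 passed among the mitotic genes, 4 of 8 cytokinesis genes did (SYP111, HIK, KINESIN-12B and PLE), 1 of the cytokinin genes, ARR15, and none of the photosynthesis genes. The decreases of the named genes were largest in double mutant replicates 2 and 3, with SYP111 at 1.75 and 1.54 TPM. Replicate 1 was nearer to WT, for instance at 2.11 TPM for HIK, where WT had 1.73 to 2.39 TPM. Against WT replicate 1, the library of its number, it was lower in SYP111 (8.00 against 9.34 TPM) and HIK (2.11 against 2.39 TPM). So it was in AUR2 (2.37 against 3.55 TPM) and CYCA1;1 (2.18 against 3.13 TPM). The photosynthesis call was lost without WT replicate 1 (adjusted p = 0.181) and the cytokinin call without WT replicate 3 (0.123). The cytokinesis genes alone of the 4 passed in fry after median-of-ratios scaling (adjusted p = 0.0397). The plastid genes were called lower (adjusted p = 5.73e-04; adjusted p = 0.866 with an estimated correlation), with 7 over all genes, 3 of them higher, and 13 adjusted over the list alone. That call was lost after median-of-ratios scaling (0.0750) and without double mutant replicate 1 (0.165).

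Against WT, 116 genes were called in the double mutant, 92 higher and 24 lower, with the median gene at -0.17; 75 of the increases and 7 of the decreases were protein-coding. After median-of-ratios scaling there were 158, 130 higher and 28 lower, and 39 on both scales. The count on the deposited scale was 59 without WT replicate 1, 43 without WT replicate 3, 415 without double mutant replicate 1 and 38 without double mutant replicate 3. The excess of increases was not stable: the 415 were 153 higher and 262 lower, the 59 were 31 and 28, the 43 were 23 and 20, and array weights gave 806 higher and 3042 lower. Of the 20 named genes called, 7 passed without each library in turn: PR1, AT1G75945, AT1G13470, AT4G04293, AT3G01345, MRD1 and TPPI. Calls lost without double mutant replicate 3 included those of PCR1, AT1G58225, AT1G14250, AT1G55335, WRKY53 and WRKY40 (adjusted p = 0.177, 0.531, 0.814, 0.756, 0.764 and 0.515), and without its replicate 2 that of CAF1a (0.767). Without WT replicate 3, AT5G10760, NIMIN-2 and BGL2 lost theirs (0.158, 0.101 and 0.603), without WT replicate 1 AT3G15536 and AT3G47480 (0.0811 and 0.232), and without WT replicate 2 AT3G20365 (0.392).

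The double mutant was set against smg7-6 to find what cdkd3-1 adds. TPPI was at 0.982 ± 0.648 TPM against 8.67 ± 4.96 TPM in smg7-6 (SD, n = 3; log2 change of -2.22 relative to the median gene, SE 0.392, limma adjusted p = 2.80e-05; 0.0678 after median-of-ratios scaling). The noncoding RNA genes AT1G25175 and AT4G04223 (adjusted p = 6.86e-06 and 0.00389) and the pseudogene AT3G20365 (adjusted p = 0.0146) were lower as well, and all 3 had an adjusted p of 1.00 after median-of-ratios scaling. ATCG00960 rose by 8.61 relative to the median gene (adjusted p = 2.24e-37) and ATCG00620 fell by 3.00 (adjusted p = 1.80e-05). The salicylic acid list was not called (8 of 18 members above the median gene, adjusted p = 0.263, no member passing), so that the double mutant was not shown to differ from smg7-6 in it. All 13 jasmonate genes lay above the median gene (adjusted p = 3.58e-09; adjusted p = 0.479 with an estimated correlation), with 0 over all genes and 3 adjusted over the list alone: the defensins PDF1.3 and PDF1.2 and the jasmonate synthesis enzyme AOC1.

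The rapid stress (adjusted p = 3.96e-09), glucosinolate (6.00e-07), cold and abscisic acid (2.34e-04) and senescence genes (0.0240) were called higher than in smg7-6, with no member passing over all genes or adjusted over the list alone. With an estimated correlation these had an adjusted p = 0.639, 0.664, 0.639 and 0.815. The plastid genes were called lower (adjusted p = 6.00e-07; adjusted p = 0.976 with an estimated correlation), 4 of the 8 called over all genes being higher and 12 passing adjusted over the list alone. After median-of-ratios scaling the cold, senescence and plastid calls were lost (adjusted p = 0.0647, 0.0788 and 0.1002). They were also lost without double mutant replicate 2 (cold, 0.298), smg7-6 replicate 1 (senescence, 0.634) and smg7-6 replicate 2 (plastid, 0.225). With the replicate block the nuclear photosynthesis genes were also called lower (adjusted p = 0.0269 against 0.0684 without it). Over all genes 30 were called, 15 higher and 15 lower, of which 22 were organelle genes or structural RNA. After median-of-ratios scaling limma called 0, with 389 genes at an unadjusted p under 0.05 against 172 on the deposited scale, where the median gene was at 0.00. The count was 19 without smg7-6 replicate 1 and 15 without double mutant replicate 3, and TPPI alone of the 4 named genes passed without each library in turn. AT3G20365 and AT1G25175 lost their calls without double mutant replicate 3 (adjusted p = 0.308 and 0.304), and AT4G04223 without its replicate 1 (0.662).

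Set against cdkd3-1, the double mutant shows what smg7-6 adds. The extensin EXT3, a structural protein of the cell wall, was at 7.16 ± 2.05 against 1.65 ± 0.748 TPM (SD, n = 3; log2 change of 1.62, of which the median gene shares 0.42, SE 0.381, limma adjusted p = 0.0308), and AT2G30766, listed as the iron-regulated peptide IMA3, at 38.9 ± 27.9 against 9.31 ± 6.62 TPM (adjusted p = 0.0426). AT3G29631, annotated as a nuclease, and the pseudogene AT4G04293 were higher with adjusted p of 0.0146 and 8.50e-04. None of these 4 passed after median-of-ratios scaling, and each lost its call without cdkd3-1 replicate 1 (limma adjusted p = 0.999). Without that library the prior also fell to 7.05 degrees of freedom. All 18 salicylic acid and immune genes lay above the median gene (adjusted p = 1.21e-11; adjusted p = 0.919 with an estimated correlation), with 0 over all genes and 6 adjusted over the list alone, among them EDS16, which makes the precursor of salicylic acid, and CBP60G, a regulator of that step. Those 6 became 0 after median-of-ratios scaling. Genes with transcripts described as targets of nonsense-mediated decay were called higher (15 of 19 above the median gene, adjusted p = 0.0118; adjusted p = 0.919 with an estimated correlation), with 0 over all genes and 2 adjusted over the list alone.

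Also called higher than in cdkd3-1 were the glucosinolate (adjusted p = 7.92e-06), rapid stress (7.22e-05), jasmonate (0.0118), mitochondrial (0.0118) and senescence genes (0.0163), and lower the mitotic (0.00124), cytokinesis (0.0203) and cytokinin genes (0.0410). With an estimated correlation each had an adjusted p = 0.919, except the mitochondrial genes (adjusted p = 0.929). Only 1 member passed over all genes, a mitochondrial gene; adjusted over the list alone, 3 rapid stress genes, 5 mitochondrial genes and 1 senescence gene passed. The plastid genes were called lower (adjusted p = 0.00537; adjusted p = 0.919 with an estimated correlation) although their median lay 0.09 above that of all genes. For the mitotic, cytokinesis, cytokinin and plastid genes fry had the opposite sign to camera (adjusted p = 0.620, 0.622, 0.647 and 0.448), as the median gene rose in this comparison. After median-of-ratios scaling the cytokinesis and plastid calls were lost (0.105 and 0.332). Only the salicylic acid and glucosinolate calls held without each library in turn: the rapid stress call was lost without double mutant replicate 2 (0.226), the jasmonate call without cdkd3-1 replicate 1 (0.174), the mitotic, cytokinesis and senescence calls without double mutant replicate 3 (0.485, 0.351 and 0.398), the mitochondrial call without double mutant replicate 2 (0.430), the cytokinin call without cdkd3-1 replicate 3 (0.231), the plastid call without cdkd3-1 replicate 2 (0.944) and that of the decay targets without double mutant replicate 1 (0.145). Over all genes 11 were called, 10 higher and 1 lower, with the median gene at 0.42, and 4 of them were protein-coding. After median-of-ratios scaling limma called 0, with 973 genes at an unadjusted p under 0.05 against 805 on the deposited scale. The count was 0 without cdkd3-1 replicate 1, 19 without cdkd3-1 replicate 3, and 24, 23 and 5 without double mutant replicates 1, 2 and 3.

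The interaction of the mutations asks whether the effect of cdkd3-1 differs with smg7-6 present. AT3G01345 and MRD1 had interactions of 3.51 (SE 0.416, limma adjusted p = 5.05e-13) and 3.49 (SE 0.466, adjusted p = 4.56e-10) on the log2 scale, and AT1G75945 one of -2.96 (SE 0.584, adjusted p = 3.83e-04; 0.0831 after median-of-ratios scaling); relative to the median gene they are 2.92, 2.896 and -3.55. AT3G01345 and MRD1 are near 0 TPM in each single mutant, so the double mutant cannot fall further and an interaction about the size of a single effect follows from that floor. In each of the 3 the genotypes with a mutation stood together, apart from WT: AT1G75945 was at 8.72 ± 1.56, 7.60 ± 5.22 and 7.19 ± 1.09 TPM in smg7-6, cdkd3-1 and the double mutant (SD, n = 3). PDF1.3 was called higher too (log2 interaction of 1.95, adjusted p = 0.0287; 1.00 after median-of-ratios scaling), and 4 of the 13 jasmonate genes passed adjusted over the list alone. The jasmonate list was called higher (adjusted p = 0.00866; adjusted p = 0.996 with an estimated correlation), and the salicylic acid list lower, with 1 of 18 members above the median gene, none passing over all genes and 1, PR1, adjusted over the list alone (adjusted p = 2.28e-20; adjusted p = 0.440 with an estimated correlation). After median-of-ratios scaling 5 members of the salicylic acid list passed adjusted over the list alone (fry adjusted p = 0.451).

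In the interaction, the heat shock (adjusted p = 0.00113) and rapid stress genes (0.0184) were called lower and the glucosinolate (0.00145), cold (0.00663) and mitotic genes (0.0149) higher, with no member passing either way. With an estimated correlation the heat shock genes had an adjusted p = 0.804 and the other 4 lists an adjusted p = 0.996. For the rapid stress genes fry had the opposite sign (adjusted p = 0.632). After median-of-ratios scaling the rapid stress and cold calls were lost (0.438 and 0.298). Without double mutant replicate 1 the rapid stress and mitotic calls were lost (0.857 and 0.707), and without WT replicate 2 the jasmonate, cold and glucosinolate calls (0.362, 0.455 and 0.120). Over all genes 22 were called, 20 higher and 2 lower (121 and 369 with median-of-ratios scaling and an infinite prior), with the median gene at 0.59; 16 were organelle genes or structural RNA, among them 10 small nucleolar RNA genes. After median-of-ratios scaling AT3G01345 and MRD1 remained, both higher. Without cdkd3-1 replicate 1 the count was 2 and the calls of AT3G01345 and PDF1.3 were lost (adjusted p = 0.112 and 0.894).

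Averaged over both backgrounds, immune genes stood higher with smg7-6. The salicylic acid list lay by a median of 1.18 above the median gene in smg7-6 against WT, but by 0.525 in the double mutant against cdkd3-1. After median-of-ratios scaling the latter was 0.418 (fry adjusted p = 0.644), so the average leans on the WT background. After that scaling NIMIN1 and PCR1 also set WT apart from all mutant libraries, as described below. In the deposited TPM PCR1 did not, at 48.4 TPM in cdkd3-1 replicate 1 and 61.7 TPM in WT replicate 2. PR1 (log2 change of 2.65 relative to the median gene, SE 0.392, limma adjusted p = 1.41e-08), PCR1 (adjusted p = 5.67e-05), BGL2 (adjusted p = 3.84e-04) and NIMIN1 (adjusted p = 0.00500) led the salicylic acid list, of which 6 of 18 members passed over all genes and 16 adjusted over the list alone, all higher (camera adjusted p = 2.16e-32; adjusted p = 0.138 with an estimated correlation; fry after median-of-ratios scaling 0.0314). PR1 and BGL2 did not pass after that scaling (adjusted p = 0.105 and 0.146). With the prior degrees of freedom of that scale, PR1, PCR1, BGL2 and NIMIN1 did not pass on the deposited scale (limma adjusted p from 0.259 to 0.375). WRKY53, WRKY40 and WRKY18 passed over all genes among the 14 rapid stress genes and 8 adjusted over the list alone (adjusted p = 1.58e-08; adjusted p = 0.647 with an estimated correlation), but none of them after median-of-ratios scaling over all genes. The senescence-associated gene SAG21 passed as the only 1 of its 5 (list adjusted p = 0.00392; adjusted p = 0.647 with an estimated correlation). Genes with transcripts described as targets of nonsense-mediated decay were not called (adjusted p = 0.112); after median-of-ratios scaling fry gave 0.0319, with 7 of 19 passing adjusted over the list alone, 6 of them higher.

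For the same contrast, lists called lower were the mitotic (adjusted p = 2.12e-07), cytokinesis (0.00167), photosynthesis (0.0204) and cytokinin genes (0.0218), and lists called higher the heat shock (0.00199), mitochondrial (0.0218) and glucosinolate genes (0.0400). The first 4 had an adjusted p = 0.822, 0.786, 0.939 and 0.822 with an estimated correlation, and the others 0.647, 0.939 and 0.939. Outside the mitochondrial genes, of which 2 passed over all genes, no member passed over all genes, and 1 heat shock gene passed adjusted over the list alone. The glucosinolate call was lost after median-of-ratios scaling (0.0510) and without cdkd3-1 replicate 1 (0.279), the photosynthesis call without WT replicate 1 (0.800), and the mitochondrial and cytokinin calls without WT replicate 3 (0.557 and 0.158). Over all genes 215 were called, 202 higher and 13 lower, with the median gene at 0.12, and 181 of the increases were protein-coding. After median-of-ratios scaling there were 254, 220 higher and 34 lower, and 77 on both scales. The count was 2 without cdkd3-1 replicate 1, where the prior also fell to 7.05 degrees of freedom. It was 102 without WT replicate 3, 108 and 63 without smg7-6 replicates 1 and 3, and 118 without double mutant replicate 3. Every named call was lost without at least 1 library: without cdkd3-1 replicate 1 PR1, PCR1, BGL2, WRKY53, WRKY40, WRKY18, SAG21 and AT2G30766 had adjusted p of 0.115, 0.0569, 0.215, 0.343, 0.619, 0.492, 0.209 and 0.693, and NIMIN1 had 0.115 without smg7-6 replicate 3.

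Across both backgrounds, TPPI was lower with cdkd3-1 among the named nuclear genes (log2 change of -2.33 with the median gene at -0.29, SE 0.277, limma adjusted p = 1.06e-13). Plastid RNA differed too, but an effect of cdkd3-1 on it was not told from a difference in its removal. MRD1 and AT3G01345 were called lower as well, which rests on the WT background, since both were already near 0 TPM in smg7-6. ATCG00960 rose by 9.14 relative to the median gene (SE 0.451, adjusted p = 2.03e-81; 0.0476 after median-of-ratios scaling) and ATCG00620 fell by 3.06 (SE 0.369, adjusted p = 3.10e-16; 0.00341 after that scaling). Of the plastid genes 10 passed over all genes, 3 of them higher, and 25 adjusted over the list alone, 4 of them higher (list adjusted p = 2.52e-05, lower; adjusted p = 0.988 with an estimated correlation). The rapid stress (adjusted p = 3.30e-22), salicylic acid (9.04e-11), jasmonate (1.60e-05), senescence (6.53e-05) and glucosinolate genes (0.0153) were called higher, and the photosynthesis (4.75e-05), mitotic (0.0176) and cytokinin genes (0.0270) lower. With an estimated correlation the rapid stress genes had an adjusted p = 0.184, the next 3 an adjusted p = 0.408 and the rest an adjusted p = 0.988. For the jasmonate and glucosinolate genes fry had the opposite sign (adjusted p = 0.853 and 0.680). No member of these 8 passed over all genes, and CAF1a alone, a rapid stress gene, passed adjusted over the list alone. After median-of-ratios scaling the cytokinin call was lost (0.139) and the cytokinesis list was called lower (0.0136 against 0.179). The plastid call was lost without double mutant replicate 1 (0.0523), the mitotic call without double mutant replicate 3 (0.352), the glucosinolate call without cdkd3-1 replicate 2 (0.197) and the cytokinin call without WT replicate 3 (0.259).

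For cdkd3-1 over both backgrounds 43 genes were called, 16 higher and 27 lower (412 and 175 with median-of-ratios scaling and an infinite prior), with the median gene at -0.29, and 8 were protein-coding. After median-of-ratios scaling 7 were called, 2 higher and 5 lower. The count was 12 without cdkd3-1 replicate 1 and 103 without double mutant replicate 1.

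Lists that were called in no contrast on the deposited scale included those closest to the mutated genes. The 12 genes of the CDK-activating kinase and the general transcription factor TFIIH had a lowest adjusted p of 0.720 over the contrasts, the 12 genes of RNA polymerase II and its kinases 0.385, and the 11 factors of nonsense-mediated decay and the exon junction complex 0.0635. The DNA damage response (10 members), the auxin response (5) and the evening genes of the circadian clock (10) had a lowest adjusted p of 0.312, 0.0855 and 0.928. Flowering time (5), iron status (5), microRNA pathway factors (6) and microRNA target genes (22) had 0.172, 0.189, 0.189 and 0.503. No member of these lists passed over all genes in any contrast on the deposited scale except AT2G30766 of the iron list. After median-of-ratios scaling SMG7 did, lower in the double mutant against WT and in the smg7-6 effect over both backgrounds (adjusted p = 0.0349 and 0.0260), and the evening clock gene BOA, named after its values were seen, was higher in the latter (adjusted p = 0.0366). Leaf libraries measured few genes of 9 other lists. Tested were 1 of 15 meiosis genes, 4 of 9 morning clock genes, 2 of 10 flavonoid genes, 2 of 8 phosphate starvation genes, 1 of 6 markers of flowers, 0 of 5 of roots, 0 of 5 of the shoot meristem, 2 of 7 of the stomatal lineage and 4 of 7 of vascular tissue. None of these 16 genes was called in any contrast, and after median-of-ratios scaling the recombinase DMC1 was, lower at 0.820 ± 0.0441 TPM in smg7-6 against 2.14 ± 0.215 TPM in WT (adjusted p = 0.0288) and at 0.679 ± 0.268 TPM in the double mutant (adjusted p = 0.0230).

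The effects of each mutation were compared between backgrounds that share no library. Across genes, the changes of smg7-6 against WT and of the double mutant against cdkd3-1 correlated with a Pearson's r of 0.339 and a Spearman's rho of 0.313, but no gene was called in the same direction in both (expected 0.0501 higher and 0.0018 lower) and 2 were called in opposite directions. The changes of cdkd3-1 against WT and of the double mutant against smg7-6 correlated with r = 0.242 and rho = 0.078, with 5 genes called higher and 6 called lower in both (expected 0.0140 and 0.0281) and 1 in opposite directions. After median-of-ratios scaling 0 genes were called in both, in either direction, for both mutations. That r was -0.049 without double mutant replicate 3, and the r of smg7-6 ranged from 0.096 to 0.628 over the libraries left out. Genes are not independent replicates, so these r have no p. The called genes were not concentrated near the mutated genes: within 2 Mb of SMG7, 5 of 623 tested genes were called in smg7-6 against WT (4.25 expected), and within 2 Mb of CDKD;3, 1 of 661 was called in cdkd3-1 against WT (1.85 expected).

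Comparisons against the same WT libraries share their chance values. Between smg7-6 and cdkd3-1 the r across genes was 0.695, against 0.552 simulated for unchanged groups, with a covariance of 0.0890 against 0.0385; 5 genes were called higher and 12 lower in both (0.0701 and 0.0505 for independent lists). Between smg7-6 and the double mutant the r was 0.790 against 0.532, the covariance 0.122 against 0.0308, and 49 genes were called higher and 9 lower in both (0.461 and 0.0433). Between cdkd3-1 and the double mutant the r was 0.782 against 0.511, the covariance 0.110 against 0.0331, and 11 genes were called higher and 12 lower in both (0.0861 and 0.0449). Genes called higher and lower in both were 1 and 2, 86 and 4, and 1 and 2 for the 3 pairs after median-of-ratios scaling. Over 100 simulated draws the median overlap was 1, with a highest of 40, 762 and 7499 for the 3 pairs. The draws dealt the deviations of the libraries in random order and so did not keep the resemblance of same-numbered libraries. The simulated r, covariances and overlaps are therefore no exact standard for the real ones. The 3 WT libraries are too few to split into 2 sets of at least 2, so part of the excess may come from the shared controls.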

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

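Of the 14968 genes tested, 22 had an effect of cdkd3-1 that differed between the WT background and smg7-6, by the interaction test, which was set before the data were examined. The explanations below were chosen after the result was seen. After median-of-ratios scaling 2 were called, 16 of the 22 were organelle genes or structural RNA, and 45 of 100 groupings of the libraries, the real one included, gave as many, so the count is not above what random groups give. Among the named genes the differences on the log2 scale were 3.51 for AT3G01345, 3.49 for MRD1 and -2.96 for AT1G75945, with the median gene at 0.59; relative to it they were 2.92, 2.896 and -3.55. The call of AT1G75945 was lost after median-of-ratios scaling (limma adjusted p = 0.0831), and for AT3G01345 and MRD1, near 0 TPM in each single mutant, the floor at 0 alone would give differences of about this size.

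In all 3 genes the mutants stood together and WT apart. After median-of-ratios scaling, 656 genes had every WT library above or below all 9 others, 194 higher and 462 lower, against 136 expected by chance, while smg7-6 stood apart in 135, cdkd3-1 in 58 and the double mutant in 167. That chance value treats the libraries as exchangeable, although those of a number resemble each other. Additive effects of the mutations would give the double mutant the sum of the single changes, but the interaction of -2.96 for AT1G75945 does not decide on that for these genes, since the gene was picked for its interaction and the call depends on the scaling. A difference between lines, such as a variant or a silenced locus that WT lacks and all 3 mutants share, or leaves of WT sampled in another state, could also give this pattern. After median-of-ratios scaling 12 genes set WT apart by more than 2 on the log2 scale (MRD1, AT3G01345, AT1G75945, AT1G24147, AT2G20721 and 7 others, among them the defence genes NIMIN1, PCR1 and BG3). In the deposited TPM, PCR1 and BG3 overlapped between WT and cdkd3-1 replicate 1. The 12 genes do not tell a difference between lines from an effect of the mutations. Leaf RNA of WT siblings segregating from each line would separate them.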

How the results depend on the processing

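No gene named in a comparison reversed its direction relative to the median gene: of the values tried, 1077 stayed on their side of the threshold, 372 lost and 47 gained a call. Many of these genes were named for large changes without overlap between the groups, which made a reversal unlikely from the start. For the list calls of the mutants against WT the numbers were 238 and 85, and 2 reversed: in fry, senescence (0.790) and heat shock (0.752) in cdkd3-1 against WT. Over the list calls of all comparisons fry had the opposite direction in 9, the others being the mitotic (0.620), cytokinesis (0.622), cytokinin (0.647) and plastid genes (0.448) in the double mutant against cdkd3-1, the rapid stress genes in the interaction (0.632), and the jasmonate (0.853) and glucosinolate genes (0.680) in the cdkd3-1 effect. Gene list calls, 68 in all, were 0 with an estimated correlation and 0 with fry, and 55 to 71 without each library. Comparisons below come in the order smg7-6, cdkd3-1 and the double mutant against WT, the double mutant against smg7-6 and against cdkd3-1, the interaction, and the effects of smg7-6 and of cdkd3-1 over both backgrounds.

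The counts of called genes, 102, 42, 116, 30, 11, 22, 215 and 43, became 2, 3, 3, 2, 0, 2, 1 and 4 with no filter, 48, 23, 54, 17, 1, 13, 80 and 24 with a filter at 5 TPM, 1054, 2094, 3848, 130, 1037, 75, 2573 and 3183 with array weights, and 13, 10, 17, 3, 0, 2, 49 and 14 without the trend. Where they moved more than 1.5-fold, they were 7, 234, 0, 0, 3, 327 and 11 with nuclear genes rescaled (all but the first), 3, 0, 0, 2 and 7 with median-of-ratios scaling and 3, 0, 0, 2 and 8 with quantile normalization (cdkd3-1 against WT, the next 2 of the double mutant, the interaction and cdkd3-1), 53, 10, 9 and 3 with the compared groups only (all but cdkd3-1 against WT), and 19 with a pseudocount of 0.1 (the double mutant against cdkd3-1). Alternatives chosen after the data were seen gave 585, 8, 1057, 9, 0, 3, 1146 and 13 with median-of-ratios scaling and the replicate block, 14, 8, 9, 3, 0, 2, 1 and 12 without cdkd3-1 replicate 1 and double mutant replicate 3, and 32, 4, 4, 0, 0, 1, 1 and 4 with both changes of library and scaling. They also gave 1691, 715, 2171, 361, 726, 490, 2181 and 587 on the median-of-ratios scale with an infinite prior, and 2, 3, 3, 0, 0, 1, 0 and 4 on the deposited scale with the prior degrees of freedom of the median-of-ratios scale, so that the counts rest on the moderation as well as on the scaling. The replicate block alone changed no count by more than 1.5-fold, at 108, 42, 111, 30, 10, 23, 224 and 44. Its changes of list calls against WT and smg7-6 stand in the report; it also called photosynthesis in the interaction (6.15e-04 against 0.127), ended the calls of cytokinin (0.0589) and plastid genes (0.0732) in the double mutant against cdkd3-1, where the numbers do not pair the libraries, and ended that of AT2G30766 there (0.0502). It changed no other call in the report.

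The directions of the called genes moved too. Increases and decreases, 75 and 27 in smg7-6 against WT, were 102 and 3 with nuclear genes rescaled and 22 and 27 without WT replicate 3. Array weights turned 14 and 28 in cdkd3-1 against WT into 200 and 1894, 92 and 24 in the double mutant into 806 and 3042, 10 and 1 against cdkd3-1 into 641 and 396, 20 and 2 in the interaction into 37 and 38, 202 and 13 for smg7-6 into 1472 and 1101, and 16 and 27 for cdkd3-1 into 128 and 3055. With median-of-ratios scaling and an infinite prior they were, in the order above, 1177 and 514, 572 and 143, 1277 and 894, 194 and 167, 359 and 367, 121 and 369, 1239 and 942, and 412 and 175, so that the excess of decreases with cdkd3-1 and that of increases in the interaction turned round.

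Leaving out each library gave 28 to 148, 8 to 58, 38 to 415, 15 to 43, 0 to 24, 2 to 32, 2 to 271 and 12 to 103. The correlation of effects between backgrounds, 0.339 for smg7-6 and 0.242 for cdkd3-1, ranged from 0.096 to 0.628 and from -0.049 to 0.586. For cdkd3-1 it reversed to -0.049 without double mutant replicate 3, to -0.201 without both libraries named above and to -0.180 with median-of-ratios scaling as well. With fewer libraries each test has less power, and without cdkd3-1 replicate 1 the prior fell to 7.05 degrees of freedom; otherwise the cause was not tested. Depth is unknown, so no limit from it can be given.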

Other observations

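In some families of receptor and regulator genes, more members than expected were called higher for smg7-6 over both backgrounds, although most members did not pass. These families, 68 groups of genes sharing a symbol with at least 10 tested members, were chosen after the data were seen, and all were tested by Fisher's exact test for called increases. Of 23 tested CRK genes, cysteine-rich receptor-like kinases at the cell surface, 8 were called higher where 0.290 were expected and none lower; 7 were after median-of-ratios scaling. CRK4 went from 3.47 TPM in WT and 5.54 TPM in cdkd3-1 to 16.2 TPM in smg7-6 and 15.5 TPM in the double mutant (limma adjusted p = 7.99e-05), and CRK6 from 1.45 and 2.65 TPM to 10.1 and 9.41 TPM (adjusted p = 2.17e-06). Of 20 receptor-like proteins (RLP), which lack a kinase domain, 5 were called (0.252 expected; 7 after median-of-ratios scaling), among them RLP23, a receptor of microbial peptides, at 4.89 TPM in smg7-6 against 0.788 TPM in WT (adjusted p = 3.00e-04). SOBIR1, the kinase that such proteins signal through, was higher as well, at 45.7 against 16.5 TPM (adjusted p = 0.0404). The limma p of single genes here and below are for smg7-6 over both backgrounds. Where only a pair of TPM is printed, it is smg7-6 against WT and leaves out the other genotypes behind the p.

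Of 27 WRKY transcription factors, 8 were called higher (0.341 expected; 5 after median-of-ratios scaling). WRKY40, WRKY53 and WRKY18 of these, and PAD4 below, also belong to the gene lists. Among the others were WRKY38 at 2.91 against 0.143 TPM (adjusted p = 7.70e-06) and WRKY51 at 4.30 against 0.528 TPM (adjusted p = 2.96e-05), both tied to salicylic acid. DMR6, an enzyme that removes salicylic acid, was at 31.2 against 5.78 TPM (limma adjusted p = 9.32e-05). PAD4, a partner of EDS1 in immunity, was at 5.41 against 1.58 TPM (limma adjusted p = 0.0212, and 0.0882 after median-of-ratios scaling). It was not called in smg7-6 against WT alone. NAC factors had 3 of 23 called (0.290 expected; Fisher adjusted p = 0.0494), and did not pass after that scaling (0.471). The transporter family ABCC and the ion channel family CNGC passed only after that scaling, with 3 called each (0.00530 and 0.00761) against 0 on the deposited scale. Members of a family share regulation and, in the CRK genes, sequence, so these counts are not independent. With the prior degrees of freedom of the median-of-ratios scale, 0 genes were called in this contrast on the deposited scale, so none of those named here passed. Without cdkd3-1 replicate 1 only 2 genes of the genome were called in this contrast, but after median-of-ratios scaling without it and double mutant replicate 3, 20 of the 23 CRK, 24 of the 27 WRKY and 18 of the 20 RLP genes still lay above the median gene.

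The explanations weighed next were chosen after the results were seen. The 3 plastid identifiers that rose most with cdkd3-1, picked for that and among them ATCG00960 and ATCG00970, stood higher in every library with cdkd3-1 than in every other library, with a median log2 change of 7.91, while ATCG00950, another plastid ribosomal RNA gene, did not pass (0.83, limma adjusted p = 0.577). Weaker removal of all ribosomal RNA would also raise the nuclear kind. Its 4 identifiers rose by 0.287 to 4.65 (median 0.71, median gene at -0.29), but 0 of the 4 separated these libraries, a strict demand for uneven values. AT2G01020, a nuclear one, passed on the deposited scale (adjusted p = 1.35e-20) through 41560 TPM in cdkd3-1 replicate 1 and 50470 TPM in double mutant replicate 3, and not after median-of-ratios scaling (adjusted p = 0.999). These libraries, the highest in ATCG00970, held 4.48% and 5.26% nuclear ribosomal RNA, against at most 0.523% elsewhere. The other libraries with cdkd3-1 held 0.0742% to 0.196%, within the range without it. The values thus do not decide on weaker removal. The labels name no batch of libraries and 0 of 6 shares of RNA classes separated the carriers, so a batch was not weighed, and no test here tells an effect of cdkd3-1 on these RNAs from a difference in their removal alone.

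The salicylic acid list stood higher in smg7-6 and in the double mutant. In the smg7-6 effect over both backgrounds its median lay 0.895 above the median gene on the deposited scale and 0.825 after median-of-ratios scaling. A factor per library moves the list and the median gene nearly alike, so this distance cannot test the scaling. The fry adjusted p was 0.114 on the deposited scale and 0.0314 after scaling, which also changes the moderation. Whether the p rests on the scaling is thus not decided. The uneven libraries, cdkd3-1 replicate 1 and double mutant replicate 3, do not carry the direction of the list. Without them 18 of 18 members still lay above the median gene in the double mutant against WT, where only the second of them enters. In the smg7-6 effect over both backgrounds, which holds both, 18 of 18 did so as well. After median-of-ratios scaling without both libraries fry gave 0.129 for the double mutant against WT and 0.0747 for the smg7-6 effect, with list medians of 1.185 and 0.817. Without WT replicate 1 it gave 0.0840 for smg7-6 against WT. Each of these fits has fewer libraries and so less power.

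Other groupings of the same libraries were a test set before the data were examined, except for the salicylic acid list outside the smg7-6 effect. With 3 libraries per group only 10 groupings exist, too few for a share under 0.05. Called genes were as many in 1 of 10 for smg7-6 against WT (102, next highest 39), 1 for cdkd3-1 (42, 33), 4 for the double mutant against WT (116, 833), 4 against smg7-6 (30, 89) and 5 against cdkd3-1 (11, 44). After median-of-ratios scaling these were 1 (136, 1), 1 (3, 1), 1 (158, 4), 10 (0, 1) and 10 (0, 1). Lists called on the deposited scale were as many in 5 (8, 10), 4 (6, 9), 1 (11, 10), 5 (6, 12) and 2 (11, 11). The median of the salicylic acid list after median-of-ratios scaling was as far from that of all genes in 1 (1.186, 0.900), 1 (0.804, 0.416), 1 (1.185, 0.634), 10 (0.0148, 0.507) and 1 (0.418, 0.357). The 833 came from WT replicates 1 and 2 with double mutant replicate 1, the 89 from smg7-6 replicates 1 and 2 with the same library, and the 44 from cdkd3-1 replicate 1 with double mutant replicates 1 and 3, which points to a structure of the samples. These 3 keep a same-numbered pair together; the groupings that part all 3 pairs, as the real one does, gave at most 39, 30, 20, 27 and 16 genes.

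For contrasts over all 12 libraries 100 groupings were used. The interaction reached its 22 genes in 45 (highest other 1600), its 7 lists in 52 (10), its 2 genes after median-of-ratios scaling in 14 (2797) and the distance of its salicylic acid list, 0.776, in 6 (1.345). The smg7-6 effect reached its 215 genes in 3 (412), its 254 after that scaling in 2 (686), its 10 lists in 11 (11) and the median of its salicylic acid list after that scaling, 0.825, in 1 (0.723). The cdkd3-1 effect reached its 43 genes in 14 (5595), its 9 lists in 21 (11), its 7 genes after that scaling in 1 (3) and the median of its salicylic acid list, 0.343, in 12 (0.554). These 100 ignore the replicate numbers, although libraries of a number resemble each other. Chosen after the data were seen were the 32 groupings that only swap same-numbered libraries. Under these the interaction reached its genes in 19 (highest other 62) and, after median-of-ratios scaling, in 8 (7), the cdkd3-1 effect in 3 (62) and 1 (3), and the smg7-6 effect in 1 (102) and 1 (32).

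Of 51 small nucleolar RNA genes tested, 1 was called higher and 7 lower in the cdkd3-1 effect over both backgrounds, and 1 and 10 in cdkd3-1 against WT. The median of the 51 lay 0.04 above that of all genes in the former, with 22 below it.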
